A study of Mus musculus with 8 samples.

How the data were processed

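RNA from 8 cultures of mouse mammary tumour cells was measured on 2-colour Agilent whole mouse genome arrays, with 1 sample per array. Per the labels, the sample RNA carried Cy5 and Universal Mouse Reference RNA, a mix from 11 cell lines, carried Cy3 on every array, and no dyes were swapped. All samples were taken after 36 h in 50 uM camptothecin. Groups were taken from the labels: Snd1 knockdown (3 arrays), empty vector (3 arrays), and Mtdh-knockout cells rescued with wild-type Mtdh (1 array) or W391D Mtdh (1 array).

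Per the file headers, the spot intensities are median pixel values of each dye and of the local background, extracted with Agilent Feature Extraction 11.0.1.1 and not normalized, whereas the submitters' processing notes name version 9.5.3.1. The deposited log10 ratios in the same files are Cy5 over Cy3 after that software's background subtraction and dye normalization, per the file headers. The series' deposited value table holds log2 ratios of Cy5 over Cy3 that the authors made from those log10 ratios. This was established by setting each column against its own array: r was 0.9878 to 1, the slope 1 to 1.001, and 93.9% to 98% of 41156 probes were equal within 0.01, while r with any other array was at most 0.953. Its columns had medians of 0.091, 0.105 and 0.118 (knockdown), 0.146, 0.119 and 0.116 (vector), 0.026 (wild-type rescue) and 0.035 (W391D), so they had not been centred. The deposited flags for spots well above background, saturated or non-uniform were used as the authors' software set them.

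The design had foreseen mean spot signals. The files hold median signals, which were used throughout. Signals were background-corrected with limma 3.58.1 in R 4.3.3 (normexp, offset 50) and log ratios normalized within each array by loess. Control spots (1639 per array) and spots flagged as outliers (77 to 142 per array) had weight 0 and were left out; no spot was saturated. The 43379 other spots held 41174 probes, 245 of them in more than 1 spot, whose values were averaged. Unversioned accessions were matched to current symbols in a RefSeq table of a later mouse assembly than the one the headers name, used for names and neighbours only. This named 27668 probes (18883 symbols) and left 13506 without a symbol. Where several probes measured a gene, the one with the highest mean brightness was used, giving 32053 features, and another probe's value is given, for genes the naming rule took within an experiment, where it differs in sign or by more than 1.5 times.

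Knockdown and vector were compared on features with Cy5 well above background on at least 3 of the 6 arrays (25694), with limma's lmFit and eBayes on the log2 scale and Benjamini-Hochberg adjustment, and a feature was called at an adjusted p under 0.05. The adjusted p-values of genes come from this fit. The 28 gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, again with a correlation estimated per list, and with fry, and a list needed 8 measured members. The rescue arrays have no replicates, so their differences were taken on features with Cy5 well above background on at least 1 of the 2 arrays, and a list's median was placed among 10000 random lists of equal size matched on brightness in 20 bins.

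Lists, tests and the rule for named genes were fixed before the data were examined. The rule took Snd1 and Mtdh; the 12 highest and 12 lowest called fold changes with values on all 6 arrays, no overlap between groups and the brighter group well above background on its 3 arrays, leaving out clone names; and up to 4 called members of each list with the smallest p. For the rescue arrays it took Snd1 and Mtdh, the 12 highest and lowest differences well above background on both arrays, and the 3 farthest members of each list outside the central 95% of random lists. For both experiments together it took the 10 genes called in the knockdown with the same sign and the largest smaller effect. Other members are named where a list's description needs them, and 1 gene that the rule took is not reported here.

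Slides were taken from the files: 2 slides held the 6 arrays, each with both groups. The main fit and list tests held no block, so the slide was used as a block in an alternative, and slide differences are given. Knockdown and vector arrays share replicate numbers. Deviations of same-numbered arrays from their group means correlated at 0.597, 0.325 and 0.337, so the numbers were taken to pair the arrays in another alternative. The pairing follows the slides: other pairs on the second slide correlated at 0.39 and 0.247, and pairs across slides at -0.378 to -0.498.

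Alternatives were no background correction, the software's log ratios, the series' value table, median centring, scaling between arrays, the Cy5 channel alone, other filters on dim probes, the mean of a gene's probes, blocks for replicate number and slide, array weights, a trended robust eBayes, stricter and looser thresholds, and each replicate left out. Within slide 2 only was added after the data were seen. The procedure was tested on simulated data with 50 features changed per fold among 25682. It recovered 52% of features at 1.25-fold, 82% at 1.5-fold, 94% at 2-fold and 100% at 4-fold, and 3 of 25452 unchanged features were called. Of 27 simulated lists without a shift, fry called 1 and camera 0. Simulated genes varied independently, whereas the real interferon list had an estimated correlation of 0.411. The simulation therefore cannot show how often camera at the preset correlation calls lists whose genes vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.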

Results

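Gene expression was measured in mammary tumour cells from FVB mice that carry the polyoma middle T (PyMT) transgene, all of them treated with 50 uM camptothecin (CPT) for 36 h. Camptothecin traps topoisomerase I on DNA and stalls replication forks. Each of the 8 samples was labelled with Cy5 and hybridised on its own array against a Cy3-labelled reference RNA pooled from 11 mouse cell lines. In the first experiment a wild-type PyMT line carried either a short hairpin RNA against Snd1 (3 arrays) or the empty lentiviral vector (3 arrays). In the second, a PyMT line from Mtdh-knockout mice was given back either wild-type Mtdh (1 array) or Mtdh with the W391D mutation, which binds Snd1 poorly (1 array). Snd1 is a nuclease-domain and Tudor-domain protein that acts in transcription and RNA metabolism, and Mtdh (metadherin) is its binding partner. No untreated cells were analysed here, so every difference below is one between cell populations that had all received the drug.

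The median Cy5 signal of an array lay between 158 and 363 and the median Cy5 background between 61 and 72. Between 78.02% and 88.47% of the 43379 non-control spots were well above background in Cy5. The number of arrays limits the precision. Log ratios correlated across probes at 0.979 to 0.992 within the knockdown group and at 0.978 to 0.99 within the vector group. Knockdown and vector arrays correlated at 0.854 to 0.874. The vector arrays correlated at 0.871 to 0.887 with the rescue arrays, which came from another line, and the 2 rescue arrays at 0.984 with each other. Knockdown replicate 1 and vector replicate 1 shared a slide, the other 4 arrays of the first experiment shared a second slide, and each rescue array lay on a slide of its own. The labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

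Which transcripts differ when tumour cells with less Snd1 meet camptothecin was addressed by the comparison of Snd1 knockdown with vector. The hairpin's target fell: Snd1 was 1.86-fold lower in the knockdown (log2 fold change -0.90 ± 0.06 SE, n = 3 and 3, adjusted p = 1.04e-05). Its log2 ratio to the reference was -3.23, -3.33 and -3.44 in the knockdown arrays and -2.48, -2.40 and -2.43 in the vector arrays, a difference of -0.74 on the first slide and -0.97 on the second. Mtdh did not pass the test (-0.12 ± 0.06, adjusted p = 0.118), and its second probe gave 0.05. In the knockdown arrays, p53 target genes, stress-response genes and immediate early genes rose together. Genes of mitosis, of DNA replication, and of ATR-CHK1 signalling and homologous recombination fell. Interferon-response genes fell too, though that list's adjusted p was 0.187 with an estimated correlation. Pmaip1 (Noxa), a pro-apoptotic BH3-only protein, rose 26.0-fold (log2 fold change 4.70 ± 0.05), and the cyclin-dependent kinase inhibitor Cdkn1a (p21) rose by 3.33 ± 0.05 on the log2 scale. Each of the 37 measured genes of G2/M and mitosis fell. The control was an empty vector. Knockdown arrays correlated with vector arrays at 0.854 to 0.874, against 0.871 to 0.887 for the rescue arrays of another line. These differences therefore cannot be assigned to Snd1 alone, because a difference in line, clone or gene copy number may contribute.

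Of 25694 features tested with limma, 17244 of them named genes, 6073 were higher and 5413 lower in the knockdown at an adjusted p under 0.05. Among named genes 497 were higher and 344 lower by at least 2-fold, and 136 and 33 by at least 4-fold. The 3 knockdown values did not overlap the 3 vector values for 53.1% of features, against 10% by chance. The sign was the same on both slides for 99.93% of the called features. Those features were called from both slides together, which favours a shared sign, so this share is no separate check. The differences of the 2 slides correlated at 0.949 across features, which are not independent replicates. With the slide as a block, 7259 features were higher and 6077 lower. Within the second slide alone the counts were 6730 and 5812.

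The 12 largest increases began with Tmem37, a membrane protein related to calcium channel subunits (5.55 ± 0.04, adjusted p = 6.87e-10), followed by Pmaip1 (4.70 ± 0.05). Mmp14, a membrane-bound collagenase (4.45 ± 0.07), Ripk3, a kinase of necroptotic cell death (4.37 ± 0.07), and Armcx1, a mitochondrial armadillo-repeat protein (4.33 ± 0.07), came next. The homeobox transcription factors Hoxb7 (4.31 ± 0.08) and Hoxa7 (4.23 ± 0.10), the peptide hormone precursor Cck (4.23 ± 0.07) and the thrombin receptor Thbd (4.10 ± 0.10) also rose, and from the Cy5 channel alone Cck rose by more than 1.5 times as much (mean log2 signal 14.29 against 7.32). Arhgdib (3.95 ± 0.08), the lysosomal peptidase Dpp7 (3.95 ± 0.08) and the metalloproteinase inhibitor Timp1 (3.94 ± 0.06) completed the group. Second probes gave smaller increases for Tmem37 (1.98), Mmp14 (1.23), Dpp7 (1.06) and Timp1 (3.13).

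Of the 12 largest decreases, Ifi44, Oas2, Igtp, Bst2 and Irf7 belong to the fixed list of type I interferon response genes. The GTPases Iigp1 (-3.73 ± 0.11, adjusted p = 1.73e-07), Gbp6 (-2.81 ± 0.08) and Igtp (-2.52 ± 0.08) fell, as did Ifi27l2a (-3.54 ± 0.11), Ifi44 (-2.81 ± 0.09) and the RNA sensor Oas2 (-2.53 ± 0.08). Bst2, which tethers virus particles to the cell (-2.47 ± 0.07), and Irf7, a transcription factor of the interferon response (-2.44 ± 0.10), fell as well. The others were the complement protease C1ra (-2.73 ± 0.09), the transcription factor Sox11 (-2.66 ± 0.06), the surface antigen Ly6c2 (-2.43 ± 0.08) and the matricellular protein Ccn5 (-2.41 ± 0.08). Other probes gave -2.38 for Ifi27l2a, -0.29 for Oas2 and as little as -0.22 for Sox11.

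**Figure D1:**
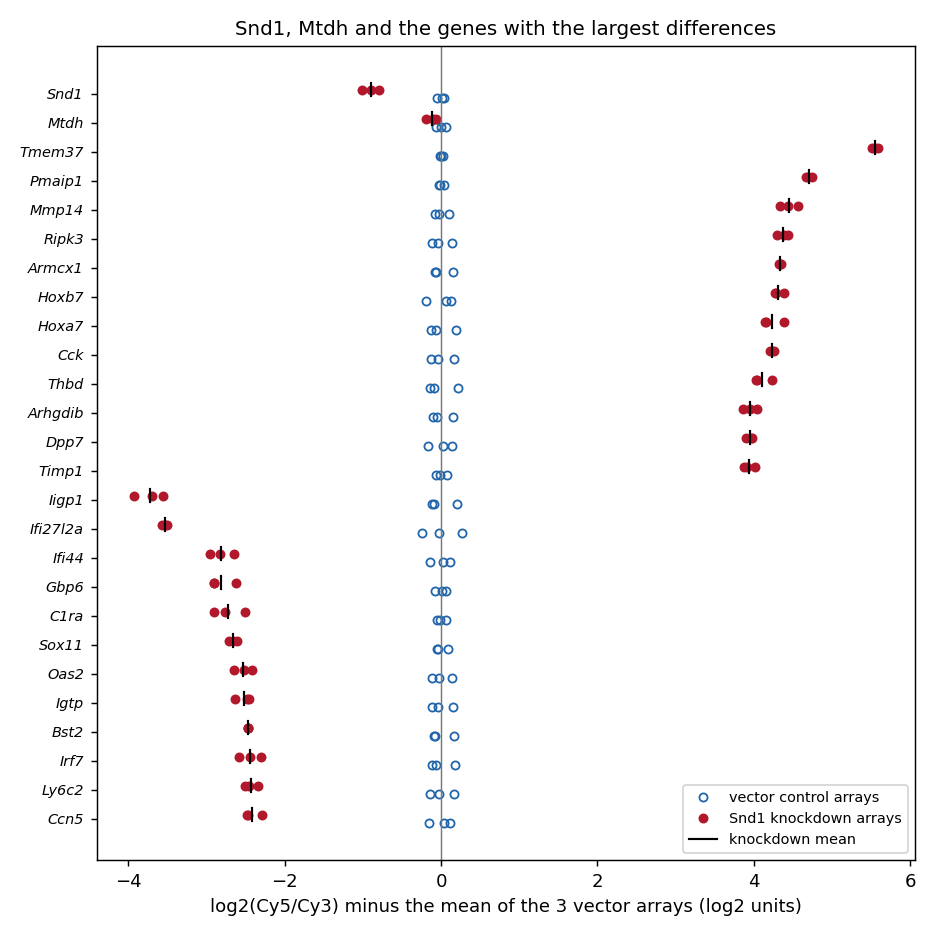
Log2(Cy5/Cy3) of Snd1, Mtdh and the 12 genes with the largest increase and decrease, as the difference from the mean of the 3 vector arrays (x axis, log2 units), 1 line per gene. Open circles are vector arrays, filled circles knockdown arrays and black bars the knockdown mean; the knockdown arrays of Tmem37 average 5.55 and those of Iigp1 -3.73, and for each gene but Mtdh the groups lie apart.

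The 28 gene lists were fixed before the data were examined and tested with camera, and 14 were called, 8 higher and 6 lower. Of 33 measured p53 targets, 23 rose and 1 fell, or 24 and 2 adjusted over the list alone (median 0.68, adjusted p = 4.65e-10; medians 0.69 and 0.67 on the 2 slides). Besides Pmaip1 and Cdkn1a (3.33 ± 0.05), Ccng1, which encodes cyclin G1 (3.1 ± 0.04), and the metabolic enzyme Dcxr (3.07 ± 0.04) rose most clearly. Fibroblast and mesenchymal lists, described further on, rose in the same arrays, with an adjusted p = 0.141 and 0.100 with an estimated correlation. Of 12 anti-apoptotic genes 6 rose and 3 fell (median 0.16, adjusted p = 0.394). The caspase-8 inhibitor Cflar (1.00 ± 0.05; 0.33 by another probe), the co-chaperone Bag3 (0.54 ± 0.04) and the Bcl-2 relative Mcl1 (0.48 ± 0.05) rose, whereas Birc5 (survivin), which also serves in mitosis, fell (-1.51 ± 0.04). Of 27 pro-apoptotic genes 10 rose and 9 fell, or 10 and 12 adjusted over the list alone (median -0.01, adjusted p = 0.983). Bbc3 (Puma; 1.33 ± 0.05) and the death receptor Fas (1.14 ± 0.05; 0.32 by another probe) rose beside Pmaip1, and Casp2 fell (-0.72 ± 0.04).

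All 37 measured G2/M and mitosis genes fell, 20 of them by at least 2-fold (median -1.01, adjusted p = 5.64e-25; -1.05 and -0.99 on the 2 slides). Cdca3, which promotes entry into mitosis (-1.64 ± 0.04), cyclin B2 (Ccnb2; -1.54 ± 0.05), Birc5 and the centromere motor Cenpe (-1.49 ± 0.05) had the smallest p-values. Of 45 DNA replication and G1/S genes 34 fell and 5 rose (median -0.47, adjusted p = 3.32e-10; -0.48 and -0.47). These included thymidine kinase (Tk1; -1.30 ± 0.05), the primase subunit Prim1 (-1.18 ± 0.05), the clamp loader subunit Rfc4 (-0.90 ± 0.04) and the ribonucleotide reductase subunit Rrm1 (-0.88 ± 0.04). Among 40 genes of ATR-CHK1 signalling and homologous recombination 30 fell and 3 rose, or 31 and 3 adjusted over the list alone (median -0.50, adjusted p = 1.32e-09; -0.52 and -0.50). The single-strand DNA binding subunit Rpa3 (-1.45 ± 0.05), the exonuclease Exo1 (-1.39 ± 0.05) and the recombination factors Rad54l (-1.19 ± 0.05) and Rad51ap1 (-1.02 ± 0.04) fell. The list of topoisomerases and repair of topoisomerase I lesions was not called (18 genes, 3 up and 8 down, median -0.07, adjusted p = 0.0691), though 4 of 20 alternatives called it lower (adjusted p from 0.0116 to 0.1). Top2a (-1.26 ± 0.05), the repair scaffold Xrcc1 (-0.79 ± 0.05), Top2b (-0.64 ± 0.04) and Top3b (-0.52 ± 0.05) fell, while Top1, the drug's target, stood at 0.05 ± 0.05 (adjusted p = 0.478). In the list of polyamine, thymidylate and nucleotide salvage enzymes 12 of 22 genes fell and 4 rose (median -0.26, adjusted p = 0.00583; -0.26 and -0.25). Its adjusted p was 0.100 with an estimated correlation. Besides Tk1, the ecto-nucleotidase Nt5e (-1.37 ± 0.07; -0.27 by another probe) and thymidylate synthase (Tyms; -0.67 ± 0.04) fell, whereas thymidine phosphorylase (Tymp; 0.93 ± 0.04) rose.

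Of 41 measured type I interferon response genes 36 fell, 17 of them by at least 2-fold, and 2 rose (median -0.94, adjusted p = 2.67e-16; -0.88 and -0.95 on the 2 slides). The list's adjusted p was 0.187 with an estimated correlation between its genes. Oasl2 (-2.38 ± 0.07), Parp14 (-2.20 ± 0.07), the GTPase Gbp3 (-2.07 ± 0.06) and Bst2 had the smallest p-values, and a second probe of Parp14 gave -0.36. The list of NF-kB targets and inflammatory cytokines moved both ways, with 15 of 35 genes up and 12 down (median 0.01, adjusted p = 0.93). In that list the cytokine Il6 (1.48 ± 0.07) and the chemokine Cxcl16 (1.00 ± 0.05) rose, and complement C3 (-2.01 ± 0.06; -0.27 by another probe) and the chemokine Ccl20 (-1.09 ± 0.07) fell.

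Of 29 immediate early genes, the transcription factors and phosphatases that answer first to stimuli, 24 rose and 1, Myc, fell (median 0.71, adjusted p = 8.02e-10; 0.74 and 0.69 on the 2 slides). Dusp2 (3.49 ± 0.08), Egr2 (2.95 ± 0.07), Btg2 (2.39 ± 0.04), which is also a p53 target, and Egr1 (2.13 ± 0.05) led them. Among 30 genes of the unfolded protein and integrated stress response 23 rose and none fell, or 24 and none adjusted over the list alone (median 0.55, adjusted p = 1.32e-09; 0.59 and 0.51). Chac1, a glutathione-degrading enzyme (2.20 ± 0.04), the chaperones' partner Dnajb9 (1.63 ± 0.04), the transcription factor Atf3 (1.21 ± 0.04) and the amino acid transporter subunit Slc3a2 (1.13 ± 0.04; 0.59 by another probe) rose. Of 19 heat shock genes 13 rose and 1 fell (median 0.42, adjusted p = 0.00056; 0.45 and 0.39), with an adjusted p = 0.158 with an estimated correlation. The small heat shock proteins Hspb8 (2.41 ± 0.06) and Hspb1 (1.85 ± 0.05) and the chaperone Hspa1a (1.1 ± 0.04) rose.

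NRF2 targets, genes of the antioxidant response, rose in 13 and fell in 6 of 26 cases, or 14 and 6 adjusted over the list alone (median 0.22, adjusted p = 0.0426; 0.23 and 0.24 on the 2 slides). Carbonyl reductase Cbr3 (3.79 ± 0.06), sulfiredoxin (Srxn1; 2.06 ± 0.04) and heme oxygenase (Hmox1; 1.42 ± 0.05) rose, and the glutathione transferase Gsta4 fell (-2.11 ± 0.06). The call on this list was lost with an estimated correlation (adjusted p = 0.395), with the replicate number as a block (0.0574), with the slide as a block (0.0569) and without vector replicate 1 (0.0711). Over 20 alternatives its adjusted p ran from 0.00603 to 0.0735.

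Genes of other cell types were examined because the cultures could hold them. Of 17 fibroblast genes 11 rose and none fell, or 12 adjusted over the list alone (median 0.36, adjusted p = 5.91e-05; 0.37 and 0.36 on the 2 slides), with an adjusted p = 0.141 with an estimated correlation. The matrix protein Postn (2.72 ± 0.04), the growth factor receptor Pdgfrb (2.44 ± 0.05), the collagen Col1a1 (2.39 ± 0.07; 0.20 by another probe) and Fbln2 (1.27 ± 0.06) rose. Among 26 genes of the epithelial-mesenchymal transition 15 rose and 4 fell, or 15 and 5 adjusted over the list alone (median 0.48, adjusted p = 0.00583; 0.47 and 0.45). Its adjusted p was 0.100 with an estimated correlation. Besides Mmp14, the transcription factor Foxc2 (2.09 ± 0.06), vimentin (Vim; 1.87 ± 0.07) and the stretch-responsive Ankrd1 (1.47 ± 0.07) rose. Of 27 luminal mammary genes 6 rose and 10 fell (median -0.07, adjusted p = 0.136). The list was called lower from the Cy5 channel alone (-0.21, adjusted p = 0.0202) and with the mean of all probes (-0.17, adjusted p = 0.0276), in a range of 0.0202 to 0.236 over 20 alternatives. The luminal transcription factor Elf5 (-2.03 ± 0.10) and keratin 8 (Krt8; -0.86 ± 0.05) fell, the epithelial factor Elf3 rose (0.69 ± 0.05), and the oestrogen receptor Esr1 fell (-0.47 ± 0.04; 0.16 by another probe). Of 20 basal and myoepithelial genes 7 rose and 8 fell (median -0.06, adjusted p = 0.854). Procr (2.00 ± 0.05) and Id4 (1.74 ± 0.10) rose, and keratin 14 (Krt14; -1.15 ± 0.07) and the contractile kinase Mylk (-1.12 ± 0.05; -0.13 by another probe) fell. From the Cy5 channel alone Krt14 fell by more than 1.5 times as much (mean log2 signal 10.10 against 12.72). Esr1 had a mean log2 signal of 6.35 against 6.93 there, and fell further still by the Feature Extraction log ratios.

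Leukocyte genes were mostly not called (2 up and 2 down of 20, or none up and 2 down adjusted over the list alone; median 0.06, adjusted p = 0.93). Cd14 (-0.47 ± 0.05) and Csf1r (-0.30 ± 0.08; 0.09 by another probe) were lower. Cd74 (0.23 ± 0.07) and Cd3e (0.14 ± 0.04) were higher, and each lost its call when any of several single arrays was left out, such as knockdown replicate 1 (0.17 and 0.12). Of 12 endothelial genes 3 rose and 2 fell (median 0.04, adjusted p = 0.394), among them the growth factor receptors Flt1 (0.72 ± 0.04) and Kdr (0.67 ± 0.07) upwards and Emcn (-0.30 ± 0.05, and more than 1.5 times as much by the Feature Extraction log ratios) downwards. Of 11 adipocyte genes 5 rose and none fell (median 0.08, adjusted p = 0.0426; 0.15 and 0.07 on the 2 slides), with an adjusted p = 0.283 with an estimated correlation. The lipid droplet protein Plin4 (1.64 ± 0.05), lipoprotein lipase (Lpl; 1.18 ± 0.06, and 0.53 by another probe), the transcription factor Pparg (0.74 ± 0.10) and the fatty acid carrier Fabp4 (0.51 ± 0.06; -0.01 by another probe) rose. The adipocyte call was lost without knockdown replicate 3 (adjusted p = 0.0628), without vector replicate 1 (0.0566) and within the second slide (0.063). Over 20 alternatives its adjusted p ran from 0.0062 to 0.063.

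Cholesterol synthesis genes fell in 19 of 25 cases and rose in 1 (median -0.47, adjusted p = 4.33e-08; -0.44 and -0.49 on the 2 slides), with an adjusted p = 0.226 with an estimated correlation. The sterol carrier Stard4 (-1.53 ± 0.08; -0.19 by another probe), the isomerase Idi1 (-1.38 ± 0.06; -0.90 by another probe) and the dehydrogenase Nsdhl (-0.86 ± 0.06) fell. Hypoxia and glycolysis genes rose in 12 and fell in 7 of 27 cases (median 0.08, adjusted p = 0.187), with Pfkfb4 (1.97 ± 0.06), Vegfa (1.48 ± 0.05; 0.44 by another probe) and the collagen-modifying enzyme P4ha2 (0.87 ± 0.05) among those that rose. Ribosome biogenesis genes moved little (8 up and 12 down of 36, median -0.04, adjusted p = 0.345), with Polr1a, the large subunit of RNA polymerase I, at -0.58 ± 0.05 and nucleolin (Ncl) at 0.45 ± 0.04 (-0.08 by another probe). Median centring called the ribosome list lower (-0.14, adjusted p = 0.0387, in a range of 0.0387 to 0.477 over 20 alternatives). Of 21 Wnt and Notch targets 2 rose and 7 fell (median -0.03, adjusted p = 0.153), with Myc at -0.69 ± 0.05 (-0.08 by another probe), Jag1 at -0.67 ± 0.07 (-0.19 by another probe) and Notch3 at 0.54 ± 0.08. Of 18 drug efflux pumps and aldehyde dehydrogenases 4 rose and 7 fell (median -0.09, adjusted p = 0.136). The efflux pump Abcg2, which carries camptothecin analogues, fell (-1.25 ± 0.04), and the pump Abcb1b rose (0.62 ± 0.07; 0.09 by another probe).

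Processes in which Snd1 itself takes part were not called by camera. Of 21 stress granule components 7 rose and 7 fell, or 9 and 7 adjusted over the list alone (median 0.02, adjusted p = 0.915). The RNA-binding protein Cirbp (0.93 ± 0.07) and the helicase Ddx3x (0.52 ± 0.05; 0.22 by another probe) rose, and G3bp2 (-0.67 ± 0.04; -0.44 by another probe) and Hnrnpa1 (-0.60 ± 0.04; 0.05 by another probe) fell. Of 17 genes of the RNA-induced silencing machinery 7 rose and 7 fell (median 0.03, adjusted p = 0.743), while fry placed them lower on balance (adjusted p = 0.000356). Tarbp2, a partner of Dicer, rose (0.82 ± 0.04), and the microRNA-processing nuclease Drosha (-0.81 ± 0.04), the helicase Mov10 (-0.70 ± 0.06) and Prkra (-0.53 ± 0.05) fell.

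The calls of the p53, ATR-CHK1, DNA replication, G2/M, stress-response and immediate early lists held with an estimated correlation, 6 of the 14. The rotation test fry, which asks only whether a list's genes move one way on balance, called 25 lists. The median of the basal list was below 0 while its mean (0.06) and its fry direction were above, and the medians of the pro-apoptotic, stress granule, silencing, NF-kB and leukocyte lists also differed in sign from their mean or camera direction; none of these 6 was called by camera. For lists with no second count given, the counts adjusted over the list alone were equal.

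**Figure D2:**
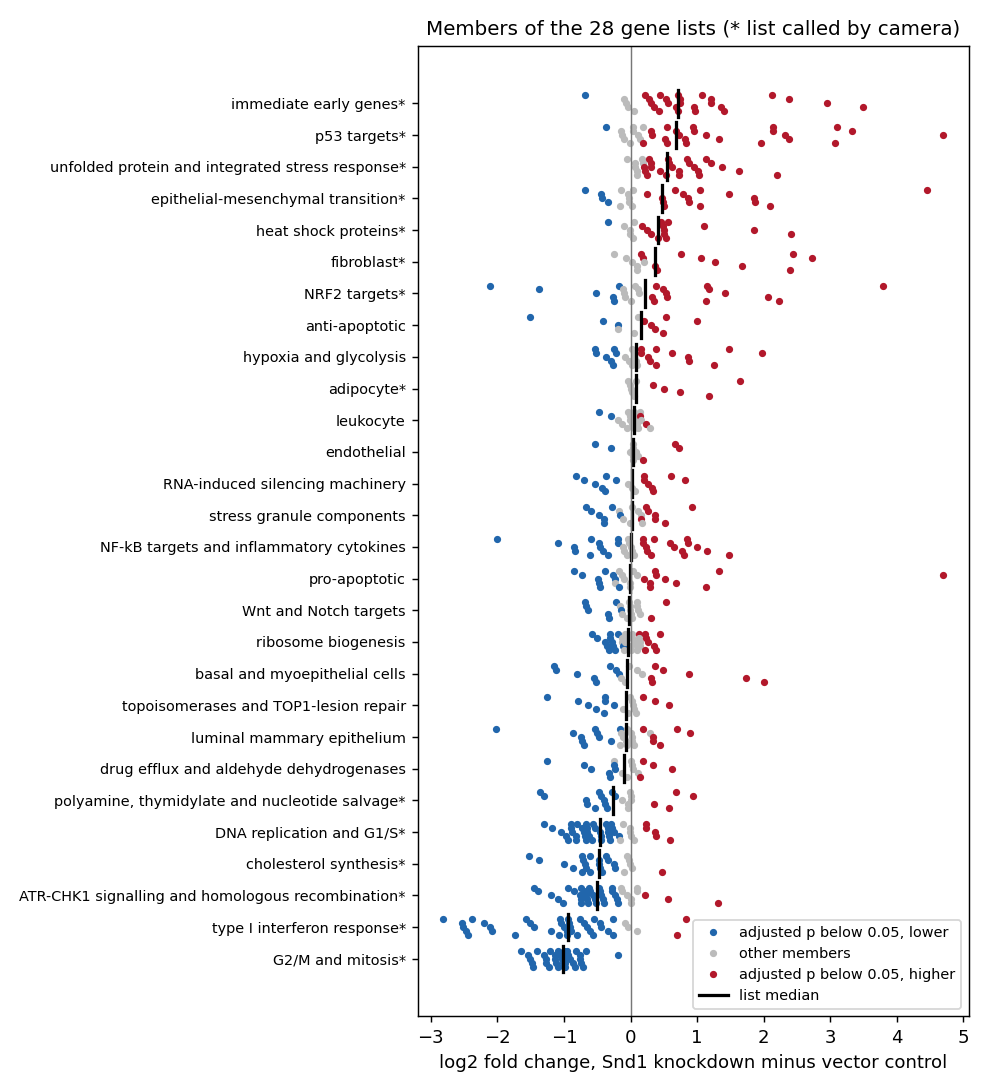
Log2 fold change of each measured member of the 28 gene lists, knockdown minus vector (x axis), with lists ordered by their median (black bar). Red and blue points are members called higher and lower, grey points are not called and an asterisk marks lists called by camera; medians run from 0.71 for immediate early genes to -1.01 for G2/M genes, all of whose points are blue.

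The second experiment asked whether the W391D mutation, which weakens the binding of Mtdh to Snd1, alters expression under camptothecin. With 1 array per group it has no replicate check, and no test was possible between its groups alone, so differences are given as sizes on the log2 scale. The 2 rescue arrays were nearly alike: of 27034 features none was higher and 1 was lower by at least 2-fold in W391D. That feature, probe A_52_P158029 (-1.0), has no gene symbol and was named after its value was seen. Arrays of one group in the first experiment differed by at least 2-fold in 41 to 68 features across slides, and in 0 and 24 on a shared slide. At 1.5-fold, 22 features were higher and 25 lower in W391D, and with the scanner software's own log ratios 140 were higher and 166 lower by 2-fold. Mtdh itself had a log2 ratio of 0.42 with the wild-type construct and -0.10 with W391D, and 0.01 and -0.16 by its other probe. Snd1 stood at -1.92 and -1.98.

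The largest increases with W391D were those of Tfpi, an inhibitor of blood coagulation (0.96), the lysosomal enzyme Hgsnat (0.92), Grrp1 (0.77), Ankk1 (0.74) and lamin B1 (Lmnb1; 0.74). Pou5f2 (0.72), Gnmt (0.71), Olfr1366 (0.68), Foxd3 (0.64), Ube2s (0.62), Spdye4b (0.61) and Galnt6 (0.61) followed. The largest decreases were those of Gen1, a resolvase of DNA recombination junctions (-0.98), Phactr2 (-0.95), the growth factor binding protein Igfbp2 (-0.94), the metalloproteinase inhibitor Timp2 (-0.74) and the glycosyltransferase Mgat3 (-0.74). St6galnac4 (-0.73), Trim30d (-0.72), Ccn5 (-0.71), Cwh43 (-0.69), Trim12a (-0.68), Cxadr (-0.68) and the tight junction protein Cldn1 (-0.68) completed the 12. Other probes gave -0.22 for Tfpi, 0.08 for Galnt6, 0.15 for Gen1, -0.23 for Mgat3, -0.19 for St6galnac4, -0.09 for Cxadr, -0.39 for Cldn1, and 0.01 for Trim30d and Trim12a. From the Cy5 channel alone Gen1 (0.42) and Foxd3 (-0.03) changed sign.

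Type I interferon genes were lower in W391D, with a list median of -0.17 that lay below all 10000 random lists of like brightness, whose central 95% ran from -0.05 to 0.04. Ifi44 (-0.56), Oas2 (-0.47) and Ifit1 (-0.41) were the farthest. The medians of 3 other lists lay below that central range: NRF2 targets (-0.07, percentile 0.52), with the glutathione transferases Mgst1 (-0.47) and Gstm1 (-0.28) and thioredoxin (Txn1; -0.26); Wnt and Notch targets (-0.07, against a central range from -0.06), with Notch3 (-0.42), Hes5 (-0.35) and Notum (-0.29); and the unfolded protein and integrated stress response (-0.05, percentile 1.84), with Vldlr (-0.32), Nupr1 (-0.27) and Chac1 (-0.23). Ribosome biogenesis (0.07, percentile 99.95), NF-kB targets (0.07, percentile 99.77) and G2/M genes (0.05, percentile 99.12) lay above it. With each array centred on its median instead of loess, the NF-kB (-0.04) and G2/M (-0.02) medians were below 0, and from the Cy5 channel alone the stress-response median was above 0. Under that centring the median over all features was itself -0.026, so the G2/M median stayed slightly above it and the NF-kB median lay below it. Rrp12 (0.27), Utp20 (0.21) and Ncl (0.19), then Mmp9 (0.43), Cxcl1 (0.39) and Ccl20 (0.28), then Espl1 (0.19), Cenpe (0.15) and Cdc25c (0.14) were the farthest in these lists. Other probes gave -0.04 for Oas2, -0.37 for Cenpe, -0.09 for Vldlr, -0.13 for Gstm1, 0.03 for Ncl and 0.09 for Cdc25c. From the Cy5 channel alone Vldlr (0.10), Chac1 (0.04) and Txn1 (0.06) changed sign, as did Cenpe (-0.03) with all its probes averaged.

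Between arrays of one group in the first experiment, no pair of 6 differed in the interferon list's median by as much as the rescue arrays, and the same held for the G2/M, NF-kB, ribosome and NRF2 lists. For the stress-response list 1 pair did, and for the Wnt and Notch list 2 pairs. Medians of the other 21 lists lay inside the central 95% of their random lists, among them the p53 targets (-0.03, percentile 13.8). Among those 21, the anti-apoptotic, pro-apoptotic, endothelial, drug efflux and polyamine lists also had no pair of 6 that differed as much. The comparison with pairs therefore does not set the lists outside the central range apart. Slide and group cannot be told apart for the rescue arrays.

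Whether the mutation moves the genes that the knockdown moves was asked by setting the differences of both experiments side by side. The 10 called genes with the largest shared change were led by Gen1 (-1.02 ± 0.07 in the knockdown and -0.98 in W391D), Tfpi (1.59 ± 0.16 and 0.96), Ankk1 (2.55 ± 0.09 and 0.74) and Timp2 (-2.05 ± 0.09 and -0.74). Trim30d (-1.09 and -0.72), Ccn5 (-2.41 and -0.71), Cxadr (-0.64 and -0.68), Aldh1a3, a retinoic acid producing enzyme (-0.70 and -0.63), Rassf4 (-1.95 and -0.62) and Npnt (-1.04 and -0.61) followed. These 10 were taken for having the same sign, so they are no evidence of agreement. Called genes with differences of like size also went opposite ways. Among them were Mgat3 (1.31 and -0.74), St6galnac4 (1.28 and -0.73), Lmnb1 (-0.95 and 0.74) and Spdye4b (-1.09 and 0.61). Genes higher in the knockdown had a median of 0.0146 in W391D and genes lower in it -0.0308, at percentiles 100 and 0 of 10000 random lists of like brightness. Those random lists treat genes as independent. Between arrays of one group in the first experiment, the same medians had an SD of 0.0112 for the former and 0.0136 for the latter. In W391D other probes turned the sign for Gen1 (0.15), Tfpi (-0.22) and Trim30d (0.01) and gave -0.09 for Cxadr, and Gen1 also turned from the Cy5 channel alone (0.42). Across 25351 features, which are not independent replicates, the differences correlated weakly (Pearson r = 0.138, Spearman correlation 0.125). The value moved with the normalization, from 0.0351 for the Cy5 channel alone to 0.18 with median centring. Median centring also turned the median of the genes higher in the knockdown to -0.03, where the W391D median over all features was -0.026. The differences had the same sign for 57.3% of called features and 63.3% of those called and at least 2-fold. No feature passed 2-fold in both. The correlation was 0.13 with the first slide's difference and 0.139 with the second's. The difference between the slides, which holds no treatment, correlated with W391D at 0.102 by Pearson and at 0.169 by Spearman, the latter above the knockdown's 0.125.

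**Figure D3:**
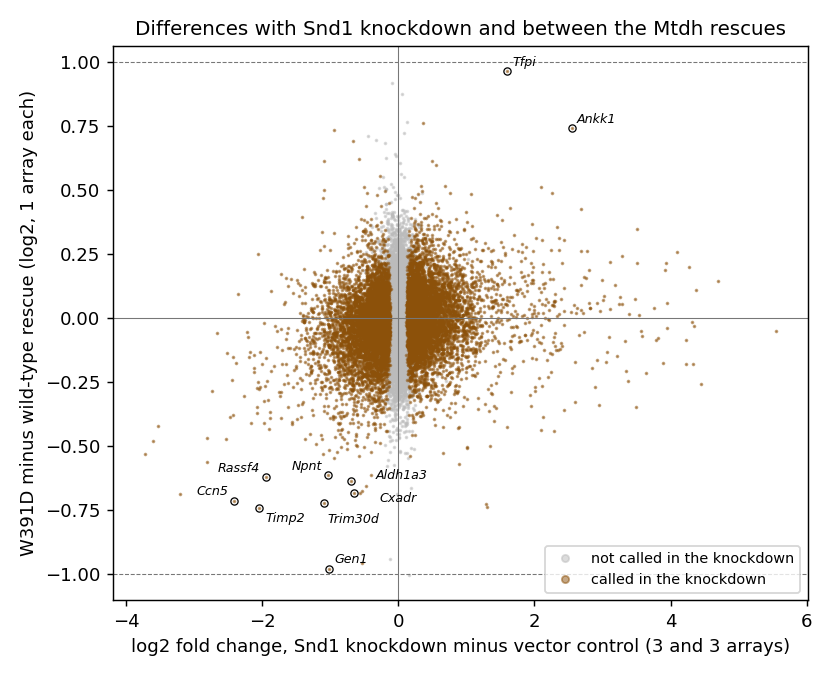
Log2 fold change of each feature in the knockdown (x axis, 3 and 3 arrays) against its log2 difference between W391D and wild-type rescue (y axis, 1 array each). Brown points are called in the knockdown, grey points are not, dashed lines mark 2-fold in W391D and circles mark the 10 named genes; the cloud is nearly round (r = 0.138) and no circled point passes a dashed line.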

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

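The comparison within slide 2 only was chosen after the result was seen; the other alternatives were fixed before the data were examined. Snd1 was lower in all 20 of its alternatives, at -1.19 to -0.84 (adjusted p from 1.16e-06 to 0.00484). The values of named knockdown genes were first counted under alternatives that kept all replicates or took slide 2 only. Of these, 1802 kept their direction and side of the threshold, 17 lost their call and 1 gained one. With a single replicate left out 771 kept both and 9 lost their call. In the former alternatives list medians kept both in 413 cases, with 17 calls lost, 17 gained and 1 direction reversed. With a single replicate left out they kept both in 165 cases, with 3 lost. The replicate block gave 6989 higher and 5900 lower features; beside the NRF2 call, which it ended (adjusted p = 0.0574), it changed no other list call and no count by more than 1.5 times. Signal over background (78.02% to 88.47% of spots in Cy5) limits what can be measured.

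Calls of at least 2-fold numbered 587 higher and 3.9e+02 lower. An estimated correlation called 6 lists and fry 25, and fry placed the basal list (-0.0551) in the upward direction (adjusted p = 0.0313). In the rescue arrays 0 features differed by 1.5 on the log2 scale, and 22 were higher and 25 lower by 1.5-fold. A limma fit of all 8 arrays, in which the lone rescue arrays are assumed to vary like the other groups, called 0 higher and 0 lower (750 and 1022 at an unadjusted p under 0.05). By 2-fold, 3 features were lower without background correction, 2 lower with scaling, 2 higher with median centring, 140 higher and 166 lower both with the software's log ratios and in the series' value table. From Cy5 alone, 6 were lower, and the genes higher in W391D than wild-type rescue by 2-fold numbered 116. The correlation of the 2 experiments was 0.0634 with the software's log ratios, 0.0633 in the value table, 0.18 with median centring, 0.0459 with scaling and 0.0351 from Cy5 alone. Under median centring genes higher in the knockdown had a W391D median of -0.0301 and genes lower in it -0.0892; from Cy5 alone the former was 0.00247, and 3628 features were called higher. With median centring the list median, W391D minus wild-type: G2/M and mitosis, turned to -0.0216. List medians also changed sign with median centring for NF-kB targets (-0.0354) and with scaling for hypoxia (-0.105). From Cy5 alone the list median, W391D minus wild-type: unfolded protein and integrated stress response, was 0.00407. With median centring the W391D difference had a median of -0.0259 over all features, against -0.00117 in the main analysis. The sign changes under median centring therefore partly reflect a shift of all features. Beyond that, the cause of these changes was not tested.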

Other observations

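The tests of another cell line, of other abundant fibroblast transcripts and of the slide behind the interferon genes, and the account of the Hox genes, were chosen only after the result was seen.

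Hoxb7 and Hoxa7 were among the highest genes in the Snd1 knockdown, and the other homeobox genes of the Hox clusters, which set position along the body axis, were looked at for that reason, with no test of enrichment. Of 31 measured, 20 were called higher and none lower (median 1.08), where 6073 of all 25694 features were called higher, and some of the 20 were not well above background on every vector array. Beside Hoxb7 (4.31 ± 0.08) and Hoxa7 (4.23 ± 0.10), Hoxc9 (3.76 ± 0.08), Hoxb2 (3.51 ± 0.09) and Hoxb6 (3.02 ± 0.05) rose most. Hoxc9 had log2 ratios of -4.41 and -4.37 in the wild-type and W391D rescue arrays, near the vector mean of -4.50, whereas Hoxb6 had 0.04 and 0.13 against a vector mean of -1.69. The family was not recomputed under the other normalizations, apart from Hoxb7 and Hoxa7.

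The p53 targets and mesenchymal genes were higher in the knockdown, though the mesenchymal list had an adjusted p = 0.100 and the fibroblast list 0.141 with an estimated correlation. Fibroblasts in the cultures would bring all their abundant transcripts. Col1a1, Col1a2 and Col3a1 had a median of 0.398, in the direction fibroblasts would give. Col1a2, Col3a1, Dcn, Lum, Sparc and Fn1 had a median of 0.0605, far below the p53 list's 0.68. The SE of the mean of these 6 genes, 0.117, is a spread over the genes and not over arrays. These 6 genes cannot exclude fibroblasts, because Sparc and Fn1 come from the mesenchymal list, and of 17 fibroblast genes 11 rose and none fell. The luminal median (-0.0707) was below 0, the direction that a loss of luminal cells would give. It lay farther from 0 than 0.0575, the largest SD over array pairs among the other cell types' list medians. That loss would raise all other cell types alike, and their medians lay apart (-0.06 to 0.36). The cultures need not hold all those types, so this cannot exclude a loss of luminal cells. Against the slide, the p53 median was at least 0.675 on each. Medians of 100 neighbouring genes spread 2.129 times as widely as in permuted order, near the ratios of the rescue line against vector (2.172 and 2.221) and above W391D against wild-type (1.544) and pairs of arrays within a group (1.029 to 1.667), and knockdown arrays correlated with vector arrays at as little as 0.854, below the other line's highest of 0.887. A difference in gene copy number, or another line or clone in the knockdown cultures, may therefore account for part of the pattern, though neighbouring genes regulated together raise that ratio too, the neighbours' medians (-0.11 to 0.22) stay far below the p53 list's, and the effect of Snd1 itself stays open.

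Type I interferon genes were lower in the knockdown (adjusted p = 0.187 with an estimated correlation) and in W391D. Between arrays of one group the list's median differed by up to 0.137, against 0.166 between the rescue arrays, too few pairs to rule out array-to-array variation. In the knockdown the median was -0.882 or lower on each slide. For the rescue arrays, however, slide and group cannot be told apart, so the W391D part of the pattern may come from the slide. The other lists called in the knockdown that lay outside the central range of random lists in W391D went opposite ways. Medians in the knockdown and in W391D were -1.01 and 0.05 for G2/M genes, and 0.22 and -0.07 for NRF2 targets. For the stress-response list they were 0.55 and -0.05. The W391D sign turned with median centring for G2/M genes and from the Cy5 channel alone for the stress-response list.

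The 6 knockdown and vector arrays can be split in 10 ways, too few for a share under 0.05. The real split, 1 of 10, called 11486 features and the highest other split 0 (at an unadjusted p under 0.05, up to 875). Each other split mixes knockdown and vector arrays, so a large difference between the groups widens its spread and lowers its count. The contrast of counts therefore says little about chance. The real split called 14 lists, as did no other, so again 1, and the highest other called 11. For the correlation with W391D, 0.138, 3 splits were as large, and the highest other, 0.165, put both arrays of the first slide together, as did the second (0.163); within slides the correlation was 0.13 and 0.139. Of the 4 splits that part all 3 same-numbered pairs, the other 3 called 0 features and 8 to 11 lists.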
